A study of Mus musculus with 19 samples.

How the data were processed

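RNA was measured in E0771 cells, a mouse mammary carcinoma line of the C57BL/6 strain that carried the red fluorescent protein mCherry. Per the labels' protocols, lean or obese mice received the cells in a mammary fat pad, the tumors were dissociated at day 14 (midpoint) or day 21 (endpoint), and mCherry-positive cells were collected by fluorescence-activated sorting before RNA extraction and library preparation. The sample names pair lean with a chow diet and obese with a high-fat diet. The labels describe the libraries as separate tumors, so the spread between replicates is a spread between tumors.

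The authors deposited 1 table of counts, which holds whole-number counts per gene that were not normalized, for 39017 genes and 19 libraries. The submitters' processing notes name TopHat, DESeq and the mm10 genome build, without versions or roles. Per the file headers, each gene has an Ensembl identifier, a chromosome, a start and an end, which are the positions printed here. The counting tool, the annotation release, the strand setting and the filters are not given in the sources used here. Reads of genes with near-identical copies, such as histone, hemoglobin and ribosomal protein genes, and of overlapping or antisense genes could have been split or merged by the counting, so values of such genes are uncertain. Symbols were taken from the GENCODE mouse annotation by identifier, which matched 37607 of the 39017 genes.

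The deposited counts of lean endpoint replicate 4 summed to 11889188 and lay on chromosomes 1 to 4 and part of chromosome 5. Of 8411 genes on chromosomes 6 to 19, X and M with a mean of at least 50 counts in the other lean endpoint libraries, 0 had a count in this library, whereas all 3090 such genes of chromosomes 1 to 4 had counts. The design fixed before the data were examined had all 19 libraries in the fit. This library was left out, after its counts had been seen and before any test was run, because its zeros are not measurements. The counts from the planned 19 libraries are printed beside those from the 18 libraries. The other 18 libraries held 44174080 to 56996252 counts each. Across 32 pairs of libraries of the same group, the chi-square per degree of freedom over genes with at least 20 counts was 35.7 or more, so no library was a repeat of another of its group. Pairs from different groups were not compared in this way.

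Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 16352 genes, and libraries were scaled by the TMM method. A model with a mean per group was fitted to all 18 libraries, and 6 contrasts were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. These were obese against lean at midpoint, at endpoint and averaged over both, the diet by time interaction, and endpoint against midpoint in lean and in obese mice. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values, which are counts scaled to library size, were computed here from the deposited counts, and log2 CPM used a prior count of 2.

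A set of 36 gene lists, 23 of pathways and 13 of cell type markers, was fixed before the data were examined, and the 33 with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Adjusted p-values of lists were taken over the lists within a contrast. Camera with an estimated correlation and fry were further readings. With an estimated correlation, 0 of the 37 list calls made over the 6 contrasts held. After the data had been seen, an exact two-sided permutation test of the library means of every list was added at each time point.

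Genes were named by a rule fixed before the data were examined. It took, among genes past the threshold with a mean of at least 1 CPM, the 8 with the largest increase and the 8 with the largest decrease in each contrast. Genes with Gm, Rik, pseudogene, LOC, Mir or Snor names or with an identifier alone were skipped, whereas names such as AU018091 and BC002059 were kept. It added the creatine genes and Acsbg1 in the diet contrasts and up to 4 members with the smallest p of each list described. The lists whose members are named were settled after the values had been seen, as those past the threshold in a contrast, plus the creatine list. Some genes that the rule took are not reported here.

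Alternatives fixed before the data were examined were RLE normalization, no filter and a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, a fit of the compared groups alone, the replicate number as a block, the pan-leukocyte mean as a covariate, a fit without marker genes, and each library left out in turn. Further alternatives were added after the data had been seen. These were a correction for GC content and length, fits without libraries in doubt, a fit without mitochondrial and structural RNA genes, a fit of chromosomes 1 to 4 with all 19 libraries, and combinations of these. The fit of all 19 libraries over all chromosomes was the planned one and is given as an alternative. For endpoint against midpoint in obese mice, fits scaled by library totals alone were also made with and without the mitochondrial and structural RNA genes. The GC and length correction fitted, per library, the deviation of log2 CPM from the gene mean on splines of GC content and length with 5 degrees of freedom each, over genes above a mean log2 CPM of 1, and entered the fit as an offset. GC content was known for 98.6% of the 16352 genes.

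The procedure was tested on simulated counts drawn from the real libraries' means, sizes and dispersions, with 100 genes changed at each of 2 sizes. The dispersions came from the uncorrected libraries, and any GC trend added was linear. Apart from that trend, genes were drawn independently, without the correlation between genes of the real libraries. The numbers of unchanged genes called therefore set no error rate for the real libraries. For obese against lean at midpoint, over 16100 genes, it recovered 46% of genes changed by a log2 value of 1 and 96% of those changed by 2, with 6 unchanged genes called. For the endpoint comparison, over 16078 genes, it recovered 51% and 95%, with 4 unchanged genes called. With the GC trends of the real libraries added to obese against lean at midpoint, 333 unchanged genes were called over 16149 genes without the correction and 2 over 16171 genes with it. With these trends added to endpoint against midpoint in obese mice, 8804 unchanged genes were called over 16157 genes without the correction and 8 over 16137 genes with it.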

Results

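RNA was sequenced from E0771 cells, a mouse mammary carcinoma line, sorted by their mCherry fluorescence from tumors grown in lean or obese mice. The counts of 18 libraries were compared: 4 lean and 5 obese at midpoint (day 14), and 4 lean and 5 obese at endpoint (day 21). Their totals ranged from 44174080 to 56996252 counts. A further lean endpoint library, replicate 4, had 11889188 counts on chromosomes 1 to 4 and part of chromosome 5, and was left out of the comparisons. The design had planned all 19 libraries, so the number of genes called with all 19 is given beside each count. P-values of single genes and of exact tests on libraries measure the spread between tumors. Those of lists from camera do not measure this spread alone, because the correlation between genes of a list was preset. With an estimated correlation 0 of the 37 list calls held.

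The libraries differed in a trend of expression with the GC content of genes. Its slope, in log2 CPM per 10 percentage points of GC, was 0.257 ± 0.207 (SD, n = 4) in lean and 1.03 ± 0.536 (SD, n = 5) in obese libraries at midpoint. At endpoint it was -0.615 ± 0.368 (SD, n = 4) and -0.742 ± 0.165 (SD, n = 5). The lowest slope at midpoint was 0.0772 and the highest at endpoint was -0.101, so the slopes of the time points did not overlap. Lean and obese slopes at midpoint differed with p = 0.0476 in an exact two-sided permutation test (adjusted p = 0.159 over 10 tests). The trend followed the first principal component, which held 69.3% of the variance: over the 9 midpoint libraries r was -0.999 (exact p = 5.5e-06) and rho was -0.983 (exact p = 5.0e-05). The adjusted p of r was 4.4e-05 over 8 relations, and without the 2 libraries farthest from the median slope r was -0.997. Over the 9 endpoint libraries r was -0.965 (exact p = 0.000394, adjusted p = 0.000788) and rho was -0.917 (exact p = 0.00131). Without the 2 farthest libraries it was -0.731 (exact p = 0.055), so that relation rested on them.

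Transcripts of the mitochondrial genome took 10.4% ± 1.41 (SD, n = 4) of the counts in lean and 6.96% ± 1.05 (SD, n = 5) in obese libraries at midpoint. Their shares were 26.4% ± 12.4 (SD, n = 4) and 21.9% ± 3.13 (SD, n = 5) at endpoint. The midpoint groups differed with p = 0.00794 in an exact two-sided permutation test, the smallest p that 126 splits allow (adjusted p = 0.0794 over 10 tests). The 7SK RNA, a small nuclear RNA that regulates transcription elongation, took 2.43% ± 0.318 (SD, n = 4) of lean and 4.05% ± 1.81 (SD, n = 5) of obese midpoint counts. The mean log2 CPM of pan-leukocyte markers was 4.06 ± 0.286 (SD, n = 4) in lean and 3.39 ± 0.271 (SD, n = 5) in obese midpoint libraries (exact two-sided permutation p = 0.0238, adjusted p = 0.119 over 10 tests).

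**Figure D1:**
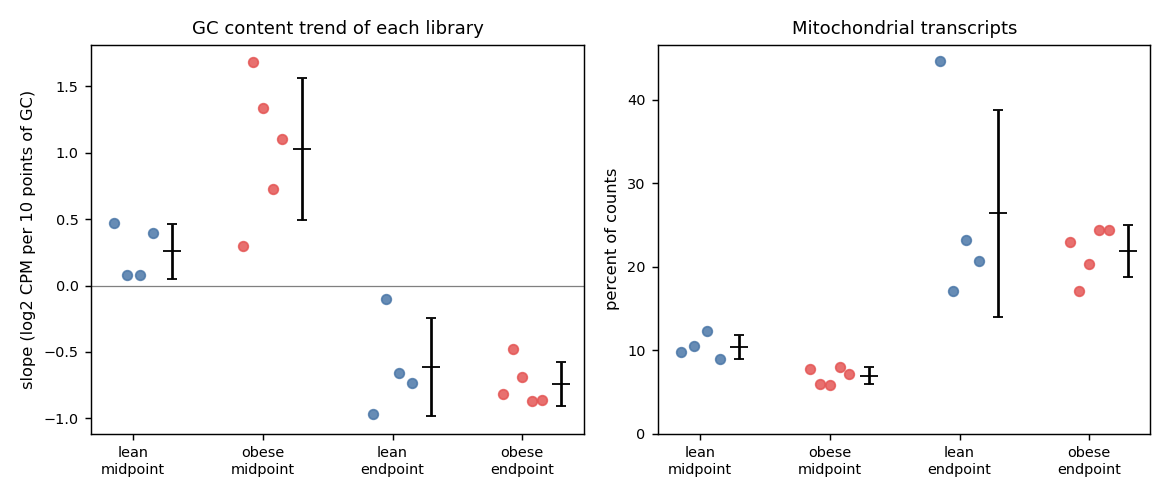
The left panel plots the slope of log2 CPM per 10 percentage points of GC content and the right panel the percentage of counts from mitochondrial transcripts, with a point per library and the mean ± SD of each group. All 9 midpoint slopes lie above 0 and all 9 endpoint slopes below it.

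Obese and lean tumors were compared at midpoint to ask how obesity of the host relates to gene expression in the cancer cells. Acsbg1, which encodes an acyl-CoA synthetase that activates long fatty acids, rose in obese tumors with a log2 fold change of 1.53 ± 0.35 (SE, 4 lean and 5 obese libraries). Its level was 5.70 ± 2.38 CPM (SD, n = 4) in lean and 16.4 ± 6.24 CPM (SD, n = 5) in obese tumors. The largest decreases included Cd53, a leukocyte tetraspanin, at -2.55 ± 0.50 (SE), Tlr13, an endosomal receptor for bacterial RNA, at -2.38 ± 0.47 (SE), Mmp12, the macrophage elastase, at -2.70 ± 0.65 (SE), and the myeloid receptors Cd200r1 at -2.80 and Clec4a2 at -2.38. Abcg3, an ABC transporter, fell by 3.10, Fgd4, an activator of Cdc42, by 2.60 and Klra2, a lectin-like receptor, by 2.40. The other genes with the largest increases were Rab4b, an endosomal GTPase (1.67), Rpph1, the RNA of ribonuclease P (1.58), Mospd3 (1.58) and the histone genes Hist1h2ak (1.60), Hist1h4n (1.58), Hist2h2ac (1.53) and Hist4h4 (1.52), whose near-identical copies make their counts uncertain. In mm10, Acsbg1 (ENSMUSG00000032281) lies on chr9 from 54604877 to 54661870 and Cd53 (ENSMUSG00000040747) on chr3 from 106758861 to 106790149.

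By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4825 of 16352 genes were called at midpoint, 2726 higher and 2099 lower (56.5% higher) in obese tumors, with a smallest adjusted p of 0.0304. With all 19 libraries 0 genes were called by the same test (1427 at unadjusted p under 0.05). DESeq2 called 6157 and limma-voom 8458 genes in the 18 libraries. Of the called genes, 33.2% were higher with no filter on low counts and 46.8% with RLE scaling, so the balance of directions depended on both choices. After correction for GC content and length 1884 genes were called. Of the 4825 calls, 1178 were kept in direction and 300 had the opposite sign. All 8 of the largest decreases and 2 of the 8 largest increases, Acsbg1 (1.10, adjusted p = 0.0324) and Hist4h4 (2.42, adjusted p = 0.0283), stayed past the threshold in that edgeR fit. No gene was called by edgeR without lean midpoint replicate 2 (5564 at unadjusted p under 0.05), lean midpoint replicate 3 (5325), obese midpoint replicate 2 (5462) or obese midpoint replicate 3 (5884). The count was 2597 without lean midpoint replicate 1, 2625 without obese midpoint replicate 5 and 7946 without obese midpoint replicate 1. Of the 38 named genes called here, 30 were kept without lean midpoint replicate 1 (lost were Adgre1, Hist1h2ak, Hist1h4n, Hist2h2ac, Mospd3, Rpl18, Rpph1 and Rpsa) and 32 without obese midpoint replicate 5 (lost were Ctss, Cxcl10, Ddx58, Gatm, Gbp3 and Hist1h4n). Hist1h4n was also lost without several single endpoint libraries. The count was 0 with the midpoint libraries fitted alone (6314 at unadjusted p under 0.05) and with the pan-leukocyte mean as a covariate (5353).

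Nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.60 over 49 genes in obese against lean midpoint tumors (camera adjusted p = 2.3e-06, and adjusted p = 0.904 with an estimated correlation). Of these 29 rose and 1 fell (32 and 1 when adjusted over the list alone), with Uqcrc1 of complex III at 0.90 and Ndufv1 of complex I at 0.88. Of 41 cytoplasmic ribosomal protein genes 16 rose and 0 fell (29 and 0 when adjusted over the list alone), among them Rpl18 (0.79), Rpsa (0.78) and Rps2 (0.75). Of 20 glycolysis genes 11 rose and 1 fell, over all genes and when adjusted over the list alone, and Slc16a3, a lactate transporter, rose by 0.82 and Gapdh by 0.74. Of 16 macrophage and monocyte markers 0 rose and 4 fell, by both counts: Itgam (-1.66), Ctss (-1.66), Adgre1 (-1.59) and Ms4a7 (-1.54). Of 9 pan-leukocyte genes 2 rose and 3 fell, by both counts, and camera did not call this list (adjusted p = 0.561). Of 29 interferon-stimulated genes 0 rose and 9 fell, by both counts, with Gbp3, a guanylate-binding protein, at -1.37, Ddx58, an RNA sensor, at -1.01 and Cxcl10, a chemokine, at -0.88.

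In camera, the list adjusted p was 2.3e-06 for oxidative phosphorylation, 1.1e-05 for ribosomal proteins, 0.0168 for glycolysis, 0.0182 for macrophage markers and 0.0313 for interferon-stimulated genes. For each of these 5 lists the adjusted p = 0.904 with an estimated correlation. The glycolysis list was no longer called after the GC and length correction (adjusted p = 0.218), and with all 19 libraries it was not called either (adjusted p = 0.607). After the correction camera called 1 list not called before. The glycolysis call was lost without lean midpoint replicate 2 (adjusted p = 0.0545). The macrophage call was lost without lean midpoint replicate 1 (0.0773), obese midpoint replicate 1 (0.145) or obese midpoint replicate 4 (0.0917), and the interferon call without lean midpoint replicate 2 (0.0812), obese midpoint replicate 1 (0.105) or obese midpoint replicate 5 (0.0524). An exact two-sided permutation test on library means gave p = 0.0159 for the interferon list (6.04 ± 0.193 in lean and 5.49 ± 0.257 log2 CPM in obese tumors, SD, n = 4 and 5) and p = 0.0476 for the macrophage list. It gave p = 0.0556 for oxidative phosphorylation, 0.0794 for ribosomal proteins and 0.0873 for glycolysis (exact permutation). The same exact permutation test gave p = 0.0159 for fatty acid uptake and activation genes, at 4.03 ± 0.0662 and 3.63 ± 0.166 log2 CPM. After the GC and length correction the difference between obese and lean means moved from -0.56 to -0.34 for the interferon list (exact permutation p = 0.00794) and from -0.40 to -0.17 for fatty acid uptake and activation (exact permutation p = 0.0238). The corrected exact permutation p was also 0.00794 for fatty acid oxidation (0.18) and for immediate early and heat shock genes (-0.37). It was 0.0397 for oxidative phosphorylation and for macrophage markers, 0.0873 for ribosomal proteins and 0.183 for glycolysis. None of these passed adjustment over 66 list tests, in which the smallest adjusted p was 0.21 before and 0.131 after the correction. The 126 splits allow no exact permutation p under 0.00794, so no list could pass unless many others also stood at that floor. The failure therefore does not count against single lists.

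Creatine genes and Acsbg1 had been chosen in advance from published work on this tumor model, which may have used these samples, so they are not an independent choice. At midpoint Slc6a8, the creatine transporter, rose by 0.63 ± 0.18 (SE) in obese tumors, from 129 ± 14.7 (SD, n = 4) to 199 ± 32.7 CPM (SD, n = 5). Gatm, the enzyme of the first step of creatine synthesis, fell by 1.18 ± 0.40 (SE), from 40.4 ± 14.97 (SD, n = 4) to 17.8 ± 14.3 CPM (SD, n = 5). The adjusted p was 0.0304 for Slc6a8 and 0.0382 for Gatm by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same test these log2 fold changes were 0.18 (adjusted p = 0.329) and -0.66 (adjusted p = 0.108) after the GC and length correction. Gamt, which completes creatine synthesis, had 0.58 (adjusted p = 0.0688), Ckb, a cytosolic creatine kinase, 0.33 (0.488) and Ckmt1, its mitochondrial counterpart, 0.24 (0.77) by edgeR. After the GC and length correction the mean log2 CPM of Gamt, Ckb and Ckmt1 was lower in obese than in lean midpoint tumors. The difference in the creatine list mean moved from 0.06 to -0.26 with the correction. Ckmt1 was near the floor, at a mean of 0.162 CPM in lean and 0.190 CPM in obese midpoint tumors. Of the 5 creatine genes tested 1 rose and 1 fell (2 and 1 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.65).

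**Figure D2:**
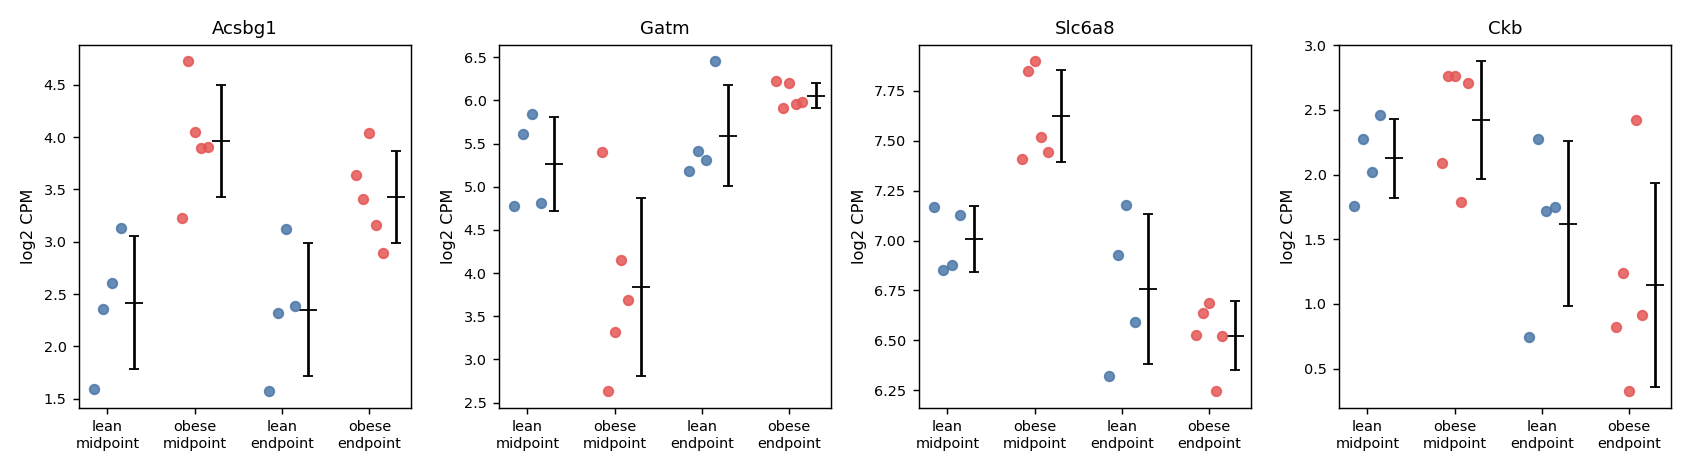
Log2 CPM of Acsbg1, Gatm, Slc6a8 and Ckb in each library, by diet and time point, with the mean ± SD of each group. Acsbg1 has a midpoint log2 fold change of 1.53 and an endpoint log2 fold change of 1.03.

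At endpoint the same question was asked, and 1 gene rose in obese tumors. This was AU018091, at 0.579 ± 0.229 CPM (SD, n = 4) in lean and 2.18 ± 0.404 CPM (SD, n = 5) in obese tumors, a log2 fold change of 1.89 ± 0.27 (SE). This gene (ENSMUSG00000054753) lies on chr7 from 3154664 to 3169203 in mm10. Acsbg1 had a log2 fold change of 1.03 ± 0.35 (SE), with 5.44 ± 2.39 CPM (SD, n = 4) in lean and 11.1 ± 3.48 CPM (SD, n = 5) in obese tumors, and did not pass (adjusted p = 0.989, edgeR). Of the creatine genes, Slc6a8 had -0.26, Gatm 0.37, Ckb -0.40, Gamt -0.13 and Ckmt1 0.69, each with an adjusted p of 0.999 by edgeR. Ckmt1 was near the floor at endpoint too, at a mean of 0.152 CPM in lean and 0.246 CPM in obese tumors.

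The adjusted p of AU018091 was 0.019 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.00545 after the GC and length correction (log2 fold change 1.91). With all 19 libraries 0 genes were called by edgeR (259 at unadjusted p under 0.05, against 800 in 18 libraries). DESeq2 called 11 genes and limma-voom 0 in the 18 libraries. The call was lost without lean endpoint replicate 1 (adjusted p = 0.0932), 2 (0.198) or 5 (0.101) and without obese endpoint replicate 1 (0.0522), 3 (0.0804) or 5 (0.0637). It was also lost with the endpoint libraries fitted alone (0 genes called by edgeR, 925 at unadjusted p under 0.05).

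All 22 genes of cholesterol synthesis had a log2 fold change below 0 in obese endpoint tumors, with a median of -0.60 (camera adjusted p = 5.8e-15, and adjusted p = 0.0875 with an estimated correlation). None passed over all genes, whereas 7 fell when adjusted over the list alone. The lowest p belonged to Pmvk, phosphomevalonate kinase, at -0.85 ± 0.23 (SE), Dhcr7, the last reductase of the pathway, at -0.77, Stard4, a sterol carrier, at -0.74, and Lss, lanosterol synthase, at -0.66. Their mean was 5.77 ± 0.0475 log2 CPM (SD, n = 4) in lean and 5.21 ± 0.183 (SD, n = 5) in obese tumors, and the groups did not overlap (5.73 to 5.84 and 4.97 to 5.44). Of 14 fatty acid synthesis genes 12 lay below 0, with Fads2, a desaturase, at -0.90 and Scd1, stearoyl-CoA desaturase, at -0.66. Of 29 interferon-stimulated genes 26 lay above 0, with Ifit1 at 0.87, Rsad2 at 0.68 and Mx2 at 0.65. For 22 inflammatory cytokine genes the median was 0.19, with Saa3 at 1.72, Il6 at 1.46 ± 0.35 (SE) and Lif at 0.78. Fibroblast markers had a median of 0.67 over 12 genes, with Col1a2 at 1.58, Postn at 1.25 and Lum at 1.14. Erythroid markers had a median of 1.73 over 6 genes, with Hba-a2 at 2.64 and Hbb-bs at 1.83, which are counts that near-identical globin copies make uncertain. The level of these markers was low, at a mean of -1.96 log2 CPM in lean and -0.812 in obese endpoint tumors. Nuclear genes of oxidative phosphorylation had a median of -0.11 over 49 genes.

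Camera called these 7 lists, and 0 of their genes passed over all genes. When adjusted over the list alone, 5 erythroid, 2 fibroblast and 2 inflammatory genes rose, and 0 interferon, fatty acid synthesis or oxidative phosphorylation genes passed. The list adjusted p was 5.8e-15 for cholesterol synthesis (adjusted p = 0.0875 with an estimated correlation) and 1.9e-09 for interferon-stimulated genes (adjusted p = 0.324 with an estimated correlation). It was 0.000836 for erythroid and 0.00673 for fibroblast markers (adjusted p = 0.228 with an estimated correlation for both). It was 0.00673 for oxidative phosphorylation (adjusted p = 0.758 with an estimated correlation), 0.00708 for fatty acid synthesis (adjusted p = 0.197 with an estimated correlation) and 0.00753 for inflammatory cytokines (adjusted p = 0.553 with an estimated correlation). With all 19 libraries the cholesterol list (adjusted p = 3.9e-06) and the erythroid list (adjusted p = 0.0125) stayed called, and the other 5 were lost. The fibroblast list (adjusted p = 0.073) and the oxidative phosphorylation list (adjusted p = 0.142) were lost after the GC and length correction, while 3 lists not called before were called by camera. The interferon call was lost without lean endpoint replicate 3 (adjusted p = 0.176), the fibroblast call without lean endpoint replicate 5 (0.0631), and the fatty acid synthesis call without lean endpoint replicate 2 (0.0864). The oxidative phosphorylation call was lost without lean endpoint replicate 2 (0.416) or obese endpoint replicate 5 (0.326), and the inflammatory call without lean endpoint replicate 3 (0.181) or 5 (0.104) or obese endpoint replicate 3 (0.0707) or 4 (0.156). Exact two-sided permutation tests on library means gave p = 0.00794 for cholesterol synthesis and for fatty acid synthesis, and p = 0.0159 for fibroblast markers, each with an adjusted p of 0.21 over 66 list tests. For the other 4 lists the exact permutation p was 0.0952 (erythroid), 0.119 (interferon), 0.159 (inflammatory cytokines) and 0.397 (oxidative phosphorylation). After the GC and length correction these became 0.0556, 0.0397, 0.111 and 0.452. The corrected exact permutation p was 0.0159 for cholesterol synthesis, 0.00794 for fatty acid synthesis and 0.0317 for fibroblast markers. The smallest corrected adjusted p over 66 list tests was 0.131. As at midpoint, 126 splits allow no exact permutation p under 0.00794, so a single list could not pass this adjustment whatever its difference.

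**Figure D3:**
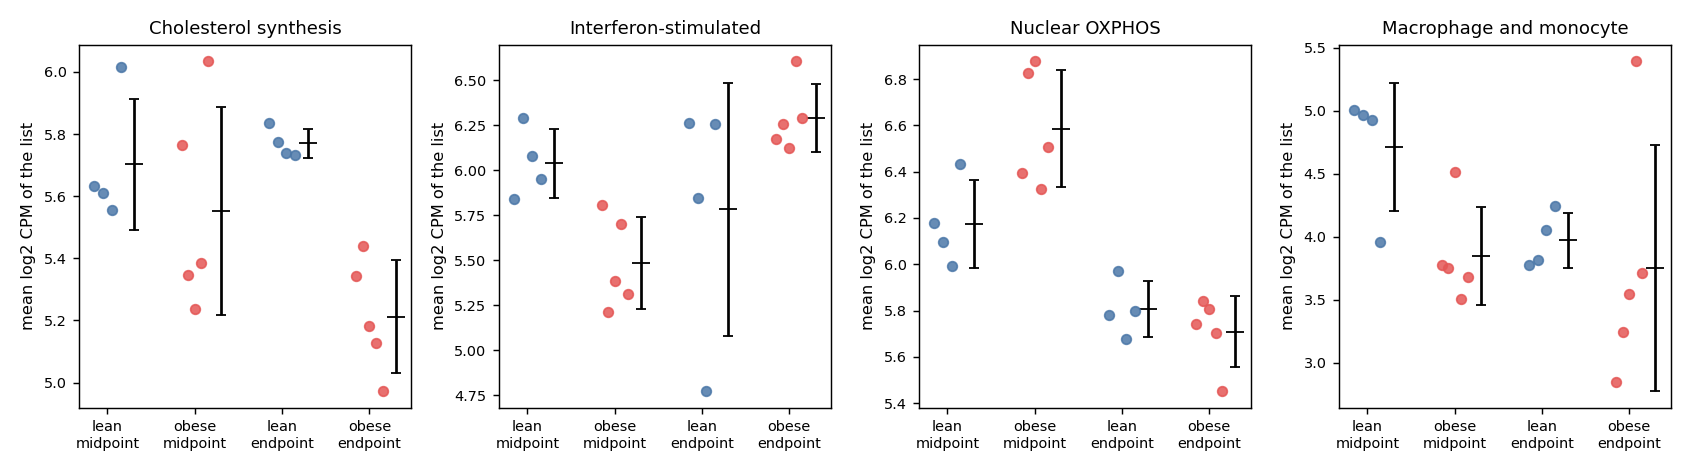
Mean log2 CPM per library of cholesterol synthesis, interferon-stimulated, nuclear oxidative phosphorylation (OXPHOS) and macrophage and monocyte genes, by diet and time point, with the mean ± SD of each group. Cholesterol synthesis means at endpoint span 5.73 to 5.84 in lean and 4.97 to 5.44 in obese tumors.

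Averaged over both time points, AU018091 rose in obese tumors by 1.24 ± 0.18 (SE, 8 lean and 10 obese libraries). Acsbg1 had a log2 fold change of 1.28 ± 0.25 (SE, adjusted p = 0.176, edgeR). Of 16 lipid storage genes 12 lay above 0 (camera adjusted p = 0.0442, and adjusted p = 0.738 with an estimated correlation), a call that was also lost after the GC and length correction. Among them were Hilpda, a lipid droplet protein, at 0.78 ± 0.20 (SE), Angptl4, an inhibitor of lipoprotein lipase, at 0.65 ± 0.16 (SE) and Plin2, a lipid droplet coat protein, at 0.53 ± 0.13 (SE), while Lpin1, a phosphatidate phosphatase, had -0.49 ± 0.13 (SE). Of 22 cholesterol synthesis genes 16 lay below 0 (camera adjusted p = 0.00099, and adjusted p = 0.738 with an estimated correlation), with Cyp51 at -0.94, Hsd17b7 at -0.75 and Hmgcs1 at -0.72. Of 22 genes of the integrated stress and unfolded protein response 16 lay above 0 (camera adjusted p = 0.027, and adjusted p = 0.738 with an estimated correlation), with Slc7a5, an amino acid transporter, at 0.63, Shmt2 of one-carbon metabolism at 0.62 and Phgdh of serine synthesis at 0.57. Each of these list members had an adjusted p of 0.218 by edgeR.

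By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 gene was called on average (AU018091, adjusted p = 0.0258), and 0 with all 19 libraries (488 at unadjusted p under 0.05). DESeq2 called 61 genes and limma-voom 4831. The AU018091 call was lost (adjusted p from 0.0575 to 0.159) without lean midpoint replicate 1, 3 or 4, obese midpoint replicate 4 or 5, lean endpoint replicate 1, 2 or 5, or obese endpoint replicate 1, 3 or 5. The count was 2655 without obese midpoint replicate 1 and 26 without obese endpoint replicate 4.

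Camera called 8 lists on average: ribosomal proteins (higher, adjusted p = 0.000158), cholesterol synthesis (lower, 0.00099), oxidative phosphorylation (higher, 0.00106), macrophage markers (lower, 0.00106), glycolysis (higher, 0.0239), the stress response (higher, 0.027), erythroid markers (higher, 0.0333) and lipid storage (higher, 0.0442). The smallest adjusted p was 0.738 with an estimated correlation, so each of the 8 calls was lost. No member of these lists passed over all genes. When adjusted over the list alone, 10 of 22 cholesterol genes fell, 4 of 16 lipid storage genes rose and 2 fell, 5 of 22 stress response genes rose, and 2 of 6 erythroid genes rose. After the GC and length correction the glycolysis (adjusted p = 0.266), erythroid (0.113) and lipid storage (0.117) calls were lost, and 6 of the 8 calls were kept with all 19 libraries. The lipid storage call was lost (adjusted p from 0.0543 to 0.102) without lean midpoint replicate 1 or 4, obese midpoint replicate 2, 3 or 4, lean endpoint replicate 1 or 5, or obese endpoint replicate 1, 2 or 4. The erythroid call was lost (0.0553 to 0.0953) without lean midpoint replicate 4, obese midpoint replicate 1, 2 or 4, lean endpoint replicate 3 or obese endpoint replicate 4. The stress response call was lost without lean midpoint replicate 4 (0.0611), lean endpoint replicate 3 (0.0856) or obese endpoint replicate 4 (0.0626), and the glycolysis call without lean midpoint replicate 2 (0.0673) or lean endpoint replicate 3 (0.0572).

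The interaction asked whether the effect of diet differed between the time points. Interferon-stimulated genes had a median difference of 1.20 over 29 genes between the obese to lean ratios at endpoint and midpoint (camera adjusted p = 2.6e-05, and adjusted p = 0.817 with an estimated correlation), including Ddx58 at 1.57, Rsad2 at 1.35, Mx2 at 1.23 and Mx1 at 1.20. Oxidative phosphorylation genes had a median difference of -0.64 over 49 genes, with Ndufv1 at -1.03 and Ndufa8 at -0.93. Cholesterol synthesis genes had a median of -0.49 over 22 genes, with Pmvk at -1.39 and Dhcr7 at -1.27. Ribosomal protein genes had a median of -0.55 and glycolysis genes of -0.62. Gatm had an interaction of 1.56 ± 0.58 (SE, adjusted p = 0.103), Slc6a8 of -0.89 ± 0.25 (SE, adjusted p = 0.0983) and Acsbg1 of -0.50 ± 0.48 (SE, adjusted p = 0.448) by edgeR.

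By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes had an interaction, with a smallest adjusted p of 0.0983 and 5451 genes at an unadjusted p under 0.05. With all 19 libraries 0 genes were called (1040 at unadjusted p under 0.05). DESeq2 called 1718 and limma-voom 5119 genes, and edgeR called 5656 without obese midpoint replicate 1. Camera called oxidative phosphorylation (lower, adjusted p = 1.6e-07), interferon-stimulated genes (higher, 2.6e-05), ribosomal proteins (lower, 7.45e-05), cholesterol synthesis (lower, 0.0271) and glycolysis (lower, 0.0274), and for each of these the adjusted p = 0.817 with an estimated correlation. When adjusted over the list alone 17 oxidative phosphorylation and 8 cholesterol genes had a lower and 12 interferon-stimulated genes a higher difference, and 0 ribosomal protein or glycolysis genes passed. The ribosomal (adjusted p = 0.231) and glycolysis (0.263) calls were lost after the GC and length correction and with all 19 libraries (0.279 and 0.909). The correction also gave calls by camera for 4 lists not called before. The cholesterol call was lost without obese midpoint replicate 1 (0.133) or 5 (0.122), lean endpoint replicate 1 (0.0549) or obese endpoint replicate 5 (0.0628), and the glycolysis call without lean midpoint replicate 2 (0.075), lean endpoint replicate 1 (0.0549) or obese endpoint replicate 5 (0.0704). RLE scaling moved the median log2 value of all genes in this contrast to 0.10. Across genes, which are not independent replicates, diet effects at midpoint and endpoint had r = -0.171 and rho = -0.209, and 40.7% of genes had the same sign. With the GC and length correction r was -0.0684.

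Endpoint and midpoint were compared in lean mice to ask how expression in the sorted cells changed as tumors grew. Lum, Dcn and the collagen genes named here are members of the fibroblast marker list, and Lum was low in lean midpoint tumors. Whether their counts came from cancer cells or from fibroblasts that passed the sort was not tested. The matrix proteoglycan genes Lum (4.14 ± 0.68, SE) and Dcn (3.96 ± 0.59, SE) rose, as did Dkk2, a Wnt inhibitor (3.39 ± 0.43, SE), Ereg, an EGF receptor ligand (3.18 ± 0.42, SE), Hmgn5 (3.77), Zfp959 (3.12) and Hspa4l (3.12). The collagen genes Col1a1 (-2.66 ± 0.46, SE) and Col1a2 (-2.15 ± 0.43, SE) fell, as did Extl1, a glycosyltransferase of heparan sulfate synthesis (-3.11 ± 0.39, SE), AU018091 (-2.72), Arsi (-2.53), Rpp25 (-2.16) and Sh3bp4 (-2.09). Lars2, a mitochondrial leucyl-tRNA synthetase, rose by 3.83 ± 1.00 (SE), with 502 ± 732 CPM (SD, n = 4) at endpoint, and its call rested on lean endpoint replicate 1, without which it had 2.02 (adjusted p = 0.0794, edgeR). Lars2 was among the genes left out in the fits without structural RNA genes. Another of these, Gm42418, took 0.752% of the counts in lean endpoint replicate 1, against 0.00534% to 0.0336% in the other lean endpoint libraries compared. Lars2 counts in that library are therefore uncertain. Of 13 T and NK cell genes 0 rose and 6 fell, with Cd4 at -1.82 and Il2rb at -1.50, at low means of -0.425 log2 CPM at midpoint and -1.47 at endpoint. Of 13 dendritic cell and MHC class II genes 1 rose and 5 fell, with H2-Aa at -1.99 and Cd74 at -1.91, and of 9 pan-leukocyte genes 0 rose and 5 fell. Of 16 macrophage markers 1 rose and 4 fell, and the 1 that rose was Mrc1, the mannose receptor, at 2.01. The Mrc1 call was lost without lean midpoint replicate 1 (adjusted p = 0.0537, edgeR) or 4 (0.0861) or lean endpoint replicate 3 (0.167), and the Rpp25 call without lean midpoint replicate 4 (0.0508). Of 16 genes of MHC class I presentation 1 rose and 8 fell (2 and 10 when adjusted over the list alone), with Tap1, the peptide transporter, at -0.84. Adjusted over the list alone, the counts of the other 4 of these lists were unchanged.

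By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5053 genes were called in lean mice, 3499 higher and 1554 lower at endpoint. With all 19 libraries 530 genes were called. After the GC and length correction 3816 genes were called. Of the 5053 calls 2340 were kept, 35 were called in the opposite direction and 410 had the opposite sign. Of the 16 genes with the largest changes, all but Rpp25 (adjusted p = 0.0922) stayed past the threshold in that edgeR fit. The count was 3251 without lean midpoint replicate 1, and 38 of the 52 named genes called here were kept without it. Of these 52, 40 were kept without lean midpoint replicate 4, 41 without lean endpoint replicate 1, 37 without lean endpoint replicate 3 and 44 without lean endpoint replicate 5.

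Of 49 oxidative phosphorylation genes in lean mice 1 rose and 13 fell at endpoint (1 and 21 when adjusted over the list alone), with Atp5o at -0.87 and Cyc1 at -0.76. Of 41 ribosomal protein genes 1 rose and 10 fell (1 and 13 when adjusted over the list alone), with Rpl24 at 1.51 and Rpl35 at -0.74. Of 20 glycolysis genes 0 rose and 3 fell (0 and 0 when adjusted over the list alone), and of 23 fatty acid oxidation genes 0 rose and 4 fell (0 and 2 when adjusted over the list alone), with Ucp2 at -1.32 and Echs1 at -0.69. The list adjusted p from camera was 1.4e-05 for oxidative phosphorylation, 0.00167 for T and NK cells, 0.00475 for MHC class I, 0.0151 for dendritic cells, 0.0441 for pan-leukocyte markers and 0.0444 for fatty acid oxidation (adjusted p = 0.662 with an estimated correlation for each). It was 0.00016 for ribosomal proteins and 0.0151 for glycolysis (adjusted p = 0.664 with an estimated correlation) and 0.0151 for macrophage markers (adjusted p = 0.693 with an estimated correlation). After the GC and length correction the ribosomal (adjusted p = 0.204), glycolysis (0.31), macrophage (0.0507) and fatty acid oxidation (0.0539) calls were lost, while 3 lists not called before were called by camera. With all 19 libraries 3 of the 9 calls were kept. The dendritic cell call was lost without lean endpoint replicate 2 (0.0624), and the macrophage call without lean midpoint replicate 2 (0.0505) or lean endpoint replicate 2 (0.0626). The pan-leukocyte call was lost without lean midpoint replicate 2 (0.1) or 3 (0.0719), obese midpoint replicate 2 (0.0543) or lean endpoint replicate 2 (0.115). The fatty acid oxidation call was lost without lean midpoint replicate 2 (0.104), obese midpoint replicate 2 (0.0543) or lean endpoint replicate 1 (0.0655) or 5 (0.0811).

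In obese mice the same comparison gave the largest number of calls. The cells that gave the counts of fibroblast markers such as Lum and Dcn were not tested here either. Lum (5.40 ± 0.64, SE) and Dcn (5.29 ± 0.56, SE) rose, with Il33, an alarmin cytokine (4.54 ± 0.61, SE), Slc40a1, the iron exporter ferroportin (4.54), Calcrl, a receptor for adrenomedullin (4.70), Spic, a transcription factor of iron-recycling macrophages (4.62), B3galt2 (5.15) and BC002059 (4.58). Extl1 (-3.19 ± 0.34, SE), Tinagl1 (-2.83), Arsi (-2.82), Agt, angiotensinogen (-2.64), Jup, a junction protein (-2.59), Gstt1 (-2.57), Aldh1l1 (-2.57) and Rny1 (-2.47) fell. Of 49 oxidative phosphorylation genes 2 rose and 43 fell, with Atp5o at -1.51 and Ndufa9 at -1.41, and of 41 ribosomal protein genes 2 rose and 35 fell, with Rps2 at -1.37. Of 20 glycolysis genes 3 rose and 15 fell, with Pfkm, a phosphofructokinase, at -1.36 and Gapdh at -1.19. Adjusted over the list alone, the counts of these 3 lists were unchanged. Of the creatine genes Gatm rose by 1.91 ± 0.39 (SE) and Gamt (-1.39), Ckb (-1.15) and Slc6a8 (-1.11) fell. With the GC and length correction these were 0.50, 0.02, 0.25 and -0.35, and Slc6a8 alone of the 4 passed (adjusted p = 0.0118, edgeR).

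By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12091 genes were called in obese mice, 6183 higher and 5908 lower at endpoint. With all 19 libraries 4213 genes were called. After the GC and length correction 9118 genes were called. Of the 12091 calls 6496 were kept, 889 were called in the opposite direction and 2563 had the opposite sign. Of the 16 genes with the largest changes, all but Agt (adjusted p = 0.1) stayed past the threshold in that edgeR fit. Camera gave adjusted p = 6.5e-08 for oxidative phosphorylation, 1.0e-05 for ribosomal proteins and 0.014 for glycolysis, and for each the adjusted p = 0.762 with an estimated correlation. After the GC and length correction the ribosomal (adjusted p = 0.127) and glycolysis (0.214) calls were lost, while 6 lists not called before were called by camera. With all 19 libraries the glycolysis call was lost (0.455). Whether the change over time differed between diets is the interaction above, in which 0 genes passed by edgeR, 5451 had an unadjusted p under 0.05, DESeq2 called 1718 and limma-voom 5119.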

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

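The corrections for GC content and length, the fits without libraries in doubt or without mitochondrial and structural RNA genes, the scaling by library totals alone, and the comparisons with other pairs of libraries, single lean libraries and other list means were tests chosen after the result was seen. The other tests here were fixed before the data were examined.

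The first pattern was the number of genes called between obese and lean tumors at midpoint. After the correction for GC content and length 24.4% of the 4825 calls were kept, and 0% to 43.9% when 1 library was also left out, so the GC trend is a candidate explanation for part of them. The same trends added to simulated counts for this comparison gave 333 calls of unchanged genes over 16149 genes. The simulated dispersions already held the GC spread within groups, and only a linear GC trend was added. The 333 calls therefore set no upper limit on what the trend gives in the real libraries. Leaving out obese midpoint replicates 2 and 3, which had the most 7SK and RNase P RNA, kept 0% of the calls. Of the other 9 pairs of obese midpoint libraries, 4 kept under 50%, each of them with replicate 2 or 3. But replicates 1 and 2 left out together kept 88.5%, 1 and 3 kept 90.5% and the pairs with neither 2 nor 3 kept 67.6% to 98.8%. Leaving out only lean midpoint replicate 2 or 3 likewise kept 0%. Obese replicates 2 and 3 had the highest GC slopes at midpoint (1.68 and 1.34). Lean replicates 2 and 3 had the lowest (0.0772 and 0.0820). Over the 9 midpoint libraries the slope followed 7SK (r = 0.952) and RNase P RNA (r = 0.935, and 0.775 without the 2 libraries farthest from the median slope). These RNAs therefore cannot be told apart from the GC trend, nor these obese libraries from those lean ones. With the pan-leukocyte mean as a covariate 0% were kept, as 19 of the other 32 list means likewise kept under 50%, so leukocytes cannot be told apart from other measures. Chance could not be excluded for this count: 5 of 80 splits of the libraries, the real one included, called at least 4825 genes, and the highest of the others called 8433, while a difference in biology between lean and obese hosts stays open.

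The next pattern was the number of genes called between endpoint and midpoint. After the correction 9118 genes were called in obese mice and 53.7% of the 12091 calls were kept, with 49.6% to 54.9% when 1 library was also left out, which argues against the GC trend as the whole source. For the calls that were lost the GC trend cannot be told apart from time, because the slopes of the time points did not overlap, and these trends added to simulated counts for this comparison gave 8804 calls of unchanged genes over 16157 genes. Without mitochondrial and structural RNA genes 96.7% of the 12091 calls were kept, which TMM scaling could give by itself. Scaling by library totals alone gave a set of calls of its own with these genes, and 95.4% of that set was kept without them. The share was 94.3% to 96.2% when 1 library was also left out. This argues against the larger mitochondrial share at endpoint as the source of the calls. In obese mice the highest of the other splits called 9005 genes against 12091 (1 of 80 splits, the real one included, reached the real count). In lean mice it called 2465 against 5053 (1 of 35). These are the smallest shares that 80 and 35 splits allow, and they were not adjusted over the comparisons tested with splits. The splits therefore argue against chance in each comparison taken alone, but do not exclude it. Tumor growth over time stays open as a biological difference. So does a batch of library preparation that follows time, since batches are not given in the sources used here.

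The last pattern was the lower level of macrophage and monocyte markers in obese than in lean tumors at midpoint, in which the groups overlapped: lean replicate 4 stood at a mean log2 CPM of 3.95 and obese replicate 3 at 4.52 (3.95 to 5.01 in lean and 3.50 to 4.52 in obese libraries). Their median log2 fold change was -1.05 after the correction for GC content and length and -0.66 before it, which argues against the GC trend as its source. A larger share of tumor cells would lower fibroblast and endothelial markers too; the highest median was 0.23 for fibroblasts before and after the correction, with list mean differences of 0.06 ± 0.23 (SE) and 0.18 ± 0.21 (SE), and the endothelial median was 0.18 before and -0.02 after it, with list mean differences of -0.06 ± 0.23 (SE) and -0.18 ± 0.22 (SE). This explanation cannot be told apart from a change in macrophages, because the endothelial median changed sign with the correction and the fibroblast list mixed Col3a1, at a mean of 1789.7 CPM in lean tumors at midpoint, with genes as low as Lum at 0.241 CPM (both named after their levels were seen). The sort for mCherry should have removed leukocytes, and these markers may come from cells that passed it or from RNA taken up by tumor cells, neither of which was tested.

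For the other comparisons, 1 of 80 splits, the real one included, reached the 1 gene called at endpoint (highest other 0), and 2 of 80 reached the 1 gene called on average. Both shares lay under the limit for chance fixed beforehand. A count of 1 against 0 separates little, however, and each call was lost without single libraries, so chance is not taken as excluded for either. The highest other split on average called 4957 genes, which points to a structure of the samples that was not tested. For the interaction the real count was 0, which all 80 splits reach whatever they call (highest other 71), so they decide nothing about chance.

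Of 200 groups of libraries tested for a library far from the others, 15 had one, and chance gives about 1 in 20. The mitochondrial 12S rRNA mt-Rnr1 took 27.9% of the counts in lean endpoint replicate 1 and 5.24% in obese endpoint replicate 5. The slope of log2 CPM per doubling of gene length was 0.260 in obese endpoint replicate 5. Mean log2 CPM stood apart for creatine genes in obese midpoint replicate 1 (3.50), cholesterol synthesis in lean midpoint replicate 4 (6.02), hypoxia response in lean endpoint replicate 1 (6.09) and the stress response in lean midpoint replicate 2 (6.24). It also did for oxidative stress genes in obese midpoint replicate 3 (6.49) and angiogenic factors in lean endpoint replicate 5 (2.54). Pan-leukocyte markers stood at 3.63 in lean midpoint replicate 4 and 3.86 in obese midpoint replicate 3, and macrophage markers at 3.95 and 4.52 in the same libraries. Endothelial markers stood at 0.34 in lean midpoint replicate 2 and -0.69 in obese endpoint replicate 1.

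The effect of diet differed between the time points for 5 lists by the interaction term in camera, each lost with an estimated correlation. The median differences of log2 CPM were -0.44 for cholesterol synthesis, -0.57 for glycolysis, -0.60 for oxidative phosphorylation, 1.18 for interferon-stimulated genes and -0.52 for ribosomal proteins. The partial library, lean endpoint replicate 4, held 11889188 counts.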

How the results depend on the processing

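The GC and length corrections, the fits without libraries in doubt or without structural RNA genes and the fits of chromosomes 1 to 4 were chosen after the result was seen. The fit of all 19 libraries was the planned one, and lean endpoint replicate 4 was left out of the main fit after its counts had been seen. The other settings were fixed before the data were examined. A result counted as unchanged if it stayed on its side of the threshold and, if called in the main fit, kept its direction. The direction of results not called there was not compared. Of 198 list results, 198 were unchanged with RLE scaling, 177 with all 19 libraries and 167 after the GC and length correction. The number was 153 with the correction and without obese midpoint replicates 2 and 3, and 143 with fry. It was 161 with an estimated correlation, where all 37 list calls were lost. Of the results of named genes, 228 were unchanged with RLE, 203 with DESeq2, 177 after the correction and 130 with all 19 libraries. The cause was not tested for the changes below, except that the fits of chromosomes 1 to 4 had fewer genes and the fits without libraries fewer samples. Each of the 18 libraries held at least 44174080 counts, and the 11889188 counts of lean endpoint replicate 4 covered part of the genome, which limits the fits that use it.

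At midpoint the 4825 calls became 8458 with limma-voom, 0 with the compared groups alone, 0 with the pan-leukocyte covariate, 0 with all 19 libraries, 1313 of the genes of chromosomes 1 to 4 with all 19, and 1884 after the GC and length correction. They became 0 without obese midpoint replicates 2 and 3, 0 without these and with the correction, 2098 without lean endpoint replicate 1 and with the correction, and 0 without all 3 and with the correction. Without 1 library they ranged from 0 to 7946. At endpoint the 1 call became 11 with DESeq2, 0 with limma-voom, 0 with the compared groups alone, 0 with all 19 libraries and 0 on chromosomes 1 to 4. It became 2 without obese midpoint replicates 2 and 3, with or without the correction, and 0 without lean endpoint replicate 1, and ranged from 0 to 1 without 1 library. On average the 1 call became 2 with no filter, 61 with DESeq2, 4831 with limma-voom, 0 with the covariate, 0 with all 19 libraries and 0 on chromosomes 1 to 4. It became 3 without obese midpoint replicates 2 and 3, 2 with the correction as well, 0 without lean endpoint replicate 1 and 2 without all 3 and with the correction, and ranged from 0 to 2655 without 1 library. The interaction's 0 calls by edgeR (5451 at unadjusted p under 0.05) became 1718 with DESeq2 and 5119 with limma-voom, and ranged from 0 to 5656 without 1 library. In lean mice the 5053 calls became 530 with all 19 libraries, 1624 on chromosomes 1 to 4 and 3000 without lean endpoint replicate 1 and with the correction, and ranged from 3251 to 6388. In obese mice the 12091 calls became 4213, 3148 on chromosomes 1 to 4, and 7831 without obese midpoint replicates 2 and 3 and with the correction.

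With the replicate number as a block, 4392 genes were called at midpoint, 0 at endpoint, 0 on average, 0 for the interaction, 3727 in lean and 11875 in obese mice. With the block and the GC and length correction, 0 were called at midpoint, 0 at endpoint and 2875 in lean mice. Correlations of the deviations of same-numbered libraries ran from -0.403 to -0.178 between lean and obese midpoint and from -0.0263 to 0.551 between lean and obese endpoint. Between obese midpoint and lean endpoint they ran from -0.161 to 0.393. Libraries with different numbers were not correlated, so these values cannot settle whether the numbers pair the samples.

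Among named genes called in the main fit, directions turned in 6. Changes of sign in named genes not called there were not counted. The settings, in order, were the GC and length correction, the correction with the block, and the correction without obese midpoint replicates 2 and 3, without lean endpoint replicate 1 and without all 3. Cycs, endpoint vs midpoint in lean, turned to -0.32, -0.37, -0.33, -0.31 and -0.32. Ndufa8, endpoint vs midpoint in obese, turned to 0.0155, 0.0169, 0.0270, 0.0169 and 0.0252. Rpl35, endpoint vs midpoint in obese, turned to 0.0681, 0.0665, 0.0419, 0.0712 and 0.0402. Ckb, endpoint vs midpoint in obese, turned to 0.248, 0.119, 0.110, 0.242 and 0.106. Gamt, endpoint vs midpoint in obese, turned to 0.0205 and 0.0118 in the first settings and 0.0201 without lean endpoint replicate 1. Etfb, endpoint vs midpoint in lean, turned to 0.00152 with the correction and block. The macrophage list at midpoint had 0.118 with the covariate, and fatty acid synthesis at endpoint 0.451 with all 19 libraries.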

Other observations

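The exact permutation tests of list means were chosen after the data had been seen. From midpoint to endpoint in obese mice 6183 of the 16352 genes rose and 5908 fell by edgeR, and camera called neither inflammatory cytokine nor T and NK cell genes. Of 22 inflammatory cytokine genes 14 rose and 3 fell from midpoint to endpoint (the same numbers when adjusted over the list alone), with a median log2 fold change of 1.06 and a camera adjusted p of 0.0595 (adjusted p = 0.762 with an estimated correlation). Of 13 T and NK cell genes 0 rose and 8 fell, with a median of -1.45 and a camera adjusted p of 0.0595 (adjusted p = 0.762 with an estimated correlation). Their level was low, at a mean of -0.236 log2 CPM at midpoint and -1.49 at endpoint in obese mice. Between diets at endpoint, mesenchymal genes had a mean of 5.81 ± 0.152 log2 CPM (SD, n = 4) in lean and 6.08 ± 0.125 (SD, n = 5) in obese tumors (exact two-sided permutation p = 0.0317, adjusted p = 0.291 over 66 tests). In the same libraries fibroblast markers had means of 2.93 ± 0.0815 (SD, n = 4) and 3.50 ± 0.294 (SD, n = 5). At midpoint, immune checkpoint ligands had a mean of 4.45 ± 0.231 (SD, n = 4) in lean and 3.98 ± 0.218 (SD, n = 5) in obese tumors (exact two-sided permutation p = 0.0476, adjusted p = 0.291 over 66 tests). These means were 4.47 and 4.14 after the GC and length correction (exact permutation p = 0.0635, adjusted p = 0.233). Macrophage markers in these libraries had means of 4.71 ± 0.507 (SD, n = 4) and 3.84 ± 0.390 (SD, n = 5), and pan-leukocyte markers of 4.06 ± 0.286 and 3.39 ± 0.271.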
